A study of Rattus norvegicus with 12 samples.

How the data were processed

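White blood cells of male Sprague Dawley rats weighing 200 to 240 g were profiled by reduced representation bisulfite sequencing, in which DNA cut with MspI is size selected, treated with bisulfite and sequenced. Per the labels, 4 libraries came from rats with no procedure, 4 from rats with sham surgery and 4 from rats with fluid percussion injury (FPI), a model of traumatic brain injury. The cells were taken 1 week after the procedure. The labels number the libraries as replicates without saying that each is a separate rat, so permutation p values measure the spread between these libraries. Those of the main site test also rest on a dispersion moderated across sites and held at or above 1, the value for sampling of reads alone. Per the labels' protocols, about 1000 ng of DNA entered each library and fragments of 150 to 300 bp were kept. The submitters' processing notes name the aligner Bowtie, whose version is not given in the sources used here, and the genome build rn5. Hippocampus, also collected in the study, was not analysed here.

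The deposited files list single cytosines. Each entry holds the methylation level as a fraction, deposited by the authors as methylated reads over all reads. The deposited read counts per cytosine, methylated and total, stand beside it and were used for every test. The smallest number of reads at any listed cytosine was 10 in the deposited files, so a coverage minimum was already in force and values from shallower cytosines were not analysed here. Filters, duplicate handling and the estimation of bisulfite conversion are not given in the sources used here.

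Reads of both strands of a CpG were summed to a dyad. Mean levels were taken, unweighted, over the 119571 dyads with at least 10 reads in all 12 libraries, on 20 autosomes and X. Groups were compared by two-sided exact permutation tests of 4 against 4 libraries, over 70 assignments, for which the smallest possible p is 0.0286. Site tests used dyads with at least 10 reads in each of the 8 libraries compared and a pooled level between 5 and 95%. For tiles, dyads of any level with at least 10 reads in each of these libraries were summed in fixed windows of 1000 bp. Tiles with at least 3 dyads and a pooled level of the tile between 5 and 95% were tested. A quasi-binomial logistic model was fitted to each dyad and tile, its dispersion was moderated across sites, and Benjamini-Hochberg adjusted p values under 0.05 were called. Mean levels are unweighted means of the libraries' levels, and differences are in percentage points.

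Comparisons, tests, the rule for named regions and the alternatives, except those said below to be added, were set before the data were examined. The first version of the site test gave too many false calls on simulated counts. The prior dispersion was then made a spline of coverage and held at or above 1, and a single prior dispersion was kept as an alternative. Corrected levels were (level - r)/(1 - r), with r the library's non-CpG level as a fraction. Tested again on simulated counts for FPI against sham, with 108066 dyads, the test called 0% of dyads changed by 10 points, 22.0% of those changed by 20, 62.0% of those changed by 30 and 96.0% of those changed by 50, with 6 false calls among 107866 unchanged dyads. For the 20761 tiles of that comparison the shares were 16.0, 80.0, 100 and 100%, with 12 false calls among 20561 unchanged tiles.

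The regions named were fixed by a rule. For each comparison these were the called tiles, up to 10 with the largest positive and 10 with the largest negative difference, for which at least 3 of 4 libraries of one group lay beyond the mean of the other. Where no tile was called, the 6 with the smallest p were named as values that did not pass. For FPI against sham, the 3 dyads with the smallest p in each direction were named too. Coordinates are rn5, as given in the deposited files. No rn5 gene annotation was used here, so gene promoters and the planned gene lists were not analysed, and regions are given without gene names.

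Alternatives were a coverage minimum of 20, no filter on level, a fit to all 12 libraries, limma 3.58.1 on log2((methylated + 1)/(unmethylated + 1)), the quasi-likelihood test of edgeR 4.0.16, thinning to 10 reads, a replicate block, leaving out each library, tile sizes of 500 and 2000 bp, strands kept apart, and a term for 2 sets of libraries. These sets are runs of consecutive accessions, with control 1 to 4 and sham 1 and 2 in the first and FPI 1 to 4 and sham 3 and 4 in the second. The term was fitted to features covered in all 12 libraries that passed the filter on level, so fewer were tested than with 8 libraries. With the term, FPI against sham rests on sham 3 and sham 4, and sham against control on sham 1 and sham 2. The libraries outside the contrast then share only the dispersion. Added after the data were seen were a correction of levels for each library's non-CpG level, libraries of 1 set only for mean levels, removal of dyads of high coverage, meaning that coverage over the library's median, averaged over the 12 libraries, was above 4, and removal of dyads at which each library lay within 15 points of 0, 50 or 100% and not all at the same of these. The single prior dispersion was also added then.

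The libraries were checked for duplicates. Over 13646 dyads of intermediate level, the mean chi-square between 2 libraries, which is 1 for sampling noise alone, was 1.14 to 3.03 over the 66 pairs, so no library was counted as a copy of another. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3 were used.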

Results

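DNA methylation was measured in white blood cells of rats 1 week after fluid percussion injury (FPI), a model of traumatic brain injury, after sham surgery, or with no procedure, with 4 libraries in each group. The depth differed between libraries. Control 1 listed 323823 CpG cytosines and FPI 4 listed 1001773. The median coverage of a CpG dyad was 12 reads in control 1 and 21 reads in FPI 4. Because files list cytosines from 10 reads upwards, a deeper library lists more of them. Over the 6 libraries of the first accession set the median coverage averaged 13.7 reads (SD 1.03), against 18.3 (SD 1.51) in the second. The reads carry no molecular identifiers in the files, so read counts describe counting error only.

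Of the 119571 dyads covered in all libraries, 36.2% had a pooled level under 5%, 26.6% had a level of 95% or more and 11.4% lay between 20 and 80%. Level followed the CpG content of the surroundings. In tiles where CpGs made up 20% or more of the listed cytosines, the mean level in control was 16.5% ± 0.219 (SD, n = 4), against 65.0% ± 0.200 (SD, n = 4) where they made up 10 to 20% and 82.9% ± 0.134 (SD, n = 4) where they made up under 10%. The 1086 dyads of the X chromosome had a mean level of 57.4% ± 0.314 (SD, n = 4) in control, 57.5% ± 0.254 in sham and 57.8% ± 0.382 in FPI.

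Non-CpG cytosines gave a measure of background in the same libraries. Their apparent level was 2.05% ± 0.276 (SD, n = 4) in control, 1.35% ± 1.11 in sham and 0.667% ± 0.491 in FPI. The spread within sham followed the 2 accession sets: sham 1 and sham 2 averaged 2.30% and sham 3 and sham 4 averaged 0.387%. The first set lay at 2.13% ± 0.266 (SD, n = 6) and the second at 0.574% ± 0.407 (SD, n = 6; two-sided exact permutation p = 0.00216). FPI 1, at 1.40%, was the exception within the second set. Mitochondrial non-CpG cytosines showed the same order, 2.04% ± 0.342 against 0.518% ± 0.491 (SD, n = 6; exact permutation p = 0.00216).

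**Figure D1:**
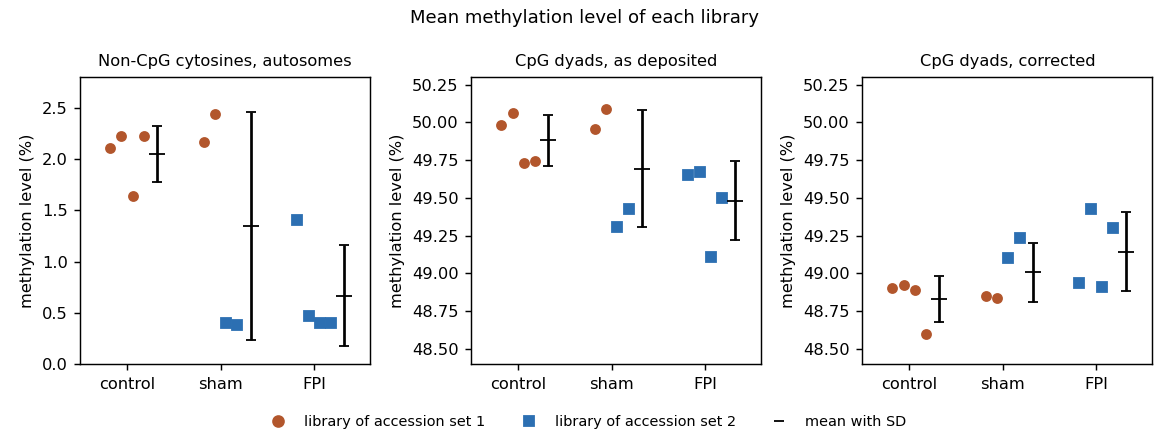
Methylation level in percent for each of the 12 libraries by group, with the mean and SD beside each group; colours and symbols give the accession set, and the vertical axes of the middle and right panels do not start at 0. Non-CpG levels of sham 1 and sham 2 averaged 2.30%, against 0.387% for sham 3 and sham 4, and mean CpG levels before correction were lower in the second set.

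The comparison of FPI with sham separates the injury from the surgery. The mean CpG level was 49.5% ± 0.259 (SD, n = 4) in FPI and 49.7% ± 0.387 (SD, n = 4) in sham, a difference of -0.212 points (two-sided exact permutation p = 0.400, adjusted p = 0.429 over 3 comparisons), less than the spread between libraries. Within the second accession set the difference was 0.117 points (4 against 2 libraries, exact permutation p = 0.600, smallest possible p 0.0667). Dense CpG tiles, with levels of 15.6% ± 0.343 in FPI and 16.1% ± 0.859 in sham (SD, n = 4), and the X chromosome, with a difference of 0.368 points, did not pass either (exact permutation p = 0.400 and 0.200).

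Of 20761 tiles, 3 were called, and all 3 were lower in FPI. On chromosome 14, from 86572001 to 86573000, the level was 69.2% ± 2.99 (SD, n = 4) in FPI and 96.8% ± 1.27 (SD, n = 4) in sham, a difference of -27.6 points (quasi-binomial model, adjusted p = 0.00177). On chromosome 6, from 71497001 to 71498000, it was 71.8% ± 2.20 and 95.3% ± 3.67, a difference of -23.5 points (adjusted p = 0.0323 in the same model). On chromosome 19, from 38560001 to 38561000, it was 77.7% ± 7.77 and 98.5% ± 1.40, a difference of -20.8 points (adjusted p = 0.0323 in the same model). The dispersion in the model was 1 on chromosome 14, 1.0026 on chromosome 6 and 1.632 on chromosome 19, where 1 is the lowest allowed. In each of these tiles every FPI library lay below every sham library. The control libraries that covered them lay at 91.5 to 100% on chromosome 14 (3 libraries), at 80.6 and 93.9% on chromosome 6 and at 82.1 to 96.4% on chromosome 19. Each tile held 3 dyads with 30 to 131 reads per library in total, and in each tile 1 dyad carried the difference. At position 86572055 of chromosome 14 FPI had 45.4% ± 3.91 and sham 97.0% ± 3.14, while the dyads at 86572064 and 86572101 differed by -2.10 and -0.132 points. At position 71497581 of chromosome 6 the levels were 44.8% ± 4.65 and 93.3% ± 6.69, with differences of -0.653 and 0.115 points at the other 2 dyads, but control 3 lay at 50% over 12 reads, within the range of the FPI libraries, and control 4 at 81.8% over 11. At position 38560096 of chromosome 19 they were 46.6% ± 27.8 and 98.6% ± 1.63, with differences of 0.563 and -1.50 points at the others. Without sham 1, sham 2, sham 3 or sham 4, the chromosome 6 tile had adjusted p = 0.0869, 0.125, 0.111 and 0.214 and the chromosome 19 tile 0.131, 0.125, 0.220 and 0.117 in the model. Without FPI 3 these were 0.0694 and 0.0576, without FPI 1 the chromosome 6 tile had 0.0643, leaving out sham 1, sham 2 or sham 4 left 1 tile called and leaving out FPI 2 gave 7. With a coverage minimum of 20, where 1867 tiles were tested, or thinning to 10 reads the quasi-binomial model called 0 tiles, with 123 and 1055 at an unadjusted p under 0.05. At that minimum the tiles of chromosomes 14 and 6 could not be tested. Sham 2 had 54 reads over the 3 dyads on chromosome 14 and 10 reads at 71497581. The chromosome 19 tile, with 60 reads over 3 dyads in FPI 3, could be tested only with exactly 20 at each. The 0 at that minimum is therefore no loss of the calls on chromosomes 14 and 6. At the deposited coverage limma called 2 tiles, both among the 3 named here, and edgeR called 3, of which 2 were among those named. Among the 8105 tiles covered in all 12 libraries that passed the filter on level, 2 were called without and 0 with a term for the accession sets, with 433 at an unadjusted p under 0.05 in both. The chromosome 14 and chromosome 6 tiles were not among these, and the chromosome 19 tile had adjusted p = 0.0363 without and 0.190 with the term.

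**Figure D2:**
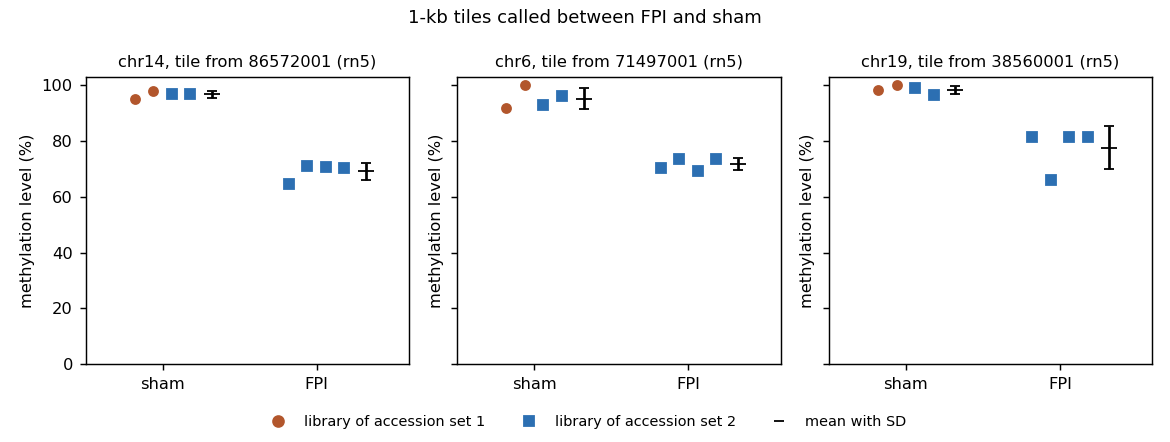
Methylation level in percent of the 3 tiles called between FPI and sham, with 1 point per library, the mean and SD beside each group, and the tile's start on rn5 above each panel. FPI means were 69.2, 71.8 and 77.7%, against sham means of 96.8, 95.3 and 98.5%.

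Of 108066 single dyads, 94 were called, 47 higher and 47 lower in FPI, on 18 chromosomes and none on X. Their median absolute difference was 42.2 points, and 79 of them had a spread of at least 30 points within at least 1 group. The 3 lower dyads with the smallest p were the ones named on chromosomes 14 and 6 and 1 on chromosome 2 at position 67736668, with 52.4% ± 1.37 in FPI and 94.3% ± 2.86 in sham (SD, n = 4). The latter was covered by 995 and 1478 reads in sham 3 and sham 4, but by 29 and 23 in sham 1 and sham 2 and 77 to 159 in FPI. Control libraries lay between 56.9% in control 3 and 90.9% in control 4 there. The 3 higher dyads were on chromosome 10 at 89176328, with 58.8% ± 9.58 against 7.46% ± 8.77, on chromosome 2 at 132362987, with 54.8% ± 18.2 against 0% ± 0, and on chromosome 2 at 109881680, with 95.3% ± 3.69 against 47.4% ± 36.0 (SD, n = 4). Rats with no procedure reached or passed the FPI mean at 2 of these 3: control 1 to control 4 had 0, 59.3, 0 and 100% on chromosome 10, and control 2 to control 4 had 94.1, 0 and 0% at 132362987, while at 109881680 controls lay at 24.6 to 48.1%. Differences were rarely shared with CpGs nearby. Of the called dyads, 92 had another dyad within 100 bp with at least 10 reads in the 8 libraries, at any level. For these 92 the median ratio of the neighbours' difference to that of the called dyad was 0.00581. Among the 44190 dyads covered in all 12 libraries that passed the filter on level, the count was 22 without and 26 with a term for the accession sets. Over all tested dyads it was 126 for FPI against sham 3 and sham 4 alone, all of the second set, of which 64 were among the 94, 11 by limma and 17 by edgeR, and leaving out FPI 2, FPI 3 or FPI 4 gave 154, 158 and 156.

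The comparison of sham with control concerns the surgery without the injury. The mean CpG level was 49.7% ± 0.387 in sham and 49.9% ± 0.168 in control (SD, n = 4), a difference of -0.186 points (two-sided exact permutation p = 0.429, adjusted p = 0.429). Within the first accession set it was 0.143 points (2 against 4 libraries, exact permutation p = 0.267). Of 47150 dyads, 146 were called, 118 higher and 28 lower in sham, and 99 of them had coverage that averaged over 4 times the median across the 12 libraries. A single stretch of chromosome 1, from 13503472 to 13505430, held 67 of these calls among its 73 dyads, all higher in sham. Its mean level was 71.2% ± 5.06 in sham and 42.7% ± 13.8 in control (SD, n = 4; difference 28.6 points, two-sided exact permutation p = 0.0286, adjusted p = 0.549 over 96 tests of stretches of high coverage). That p is the smallest possible, and with 5 of 96 tests at it none could pass after adjustment. Every sham library lay above every control library there, and coverage was 5.24 to 41.5 times the library's median. FPI libraries spread from 35.9% in FPI 1 to 79.7% in FPI 2. On chromosome 14, from 46834597 to 46834690, all 14 dyads were called, with 74.96% ± 7.86 in sham and 40.2% ± 17.2 in control (SD, n = 4; exact permutation p = 0.0286, adjusted p = 0.549). Coverage of that stretch was 1.78 to 16.3 times the median. Both stretches were chosen for description after their values were seen. Without dyads of high coverage 29 dyads were higher and 21 lower in sham, thinned to 10 reads 12 and 10, and limma called 3. Among the 46379 dyads covered in all 12 libraries that passed the filter on level, 75 were called without a term for the accession sets. With it, where only sham 1 and sham 2 stand against control and the other libraries share the dispersion, 1 was higher and 4 were lower. Fitted without the other libraries, sham 1 and sham 2 against control, all of the first set, gave 151 calls over the 47150 dyads. Of these, 88 were higher and 63 lower, and 66 were among the 146.

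**Figure D3:**
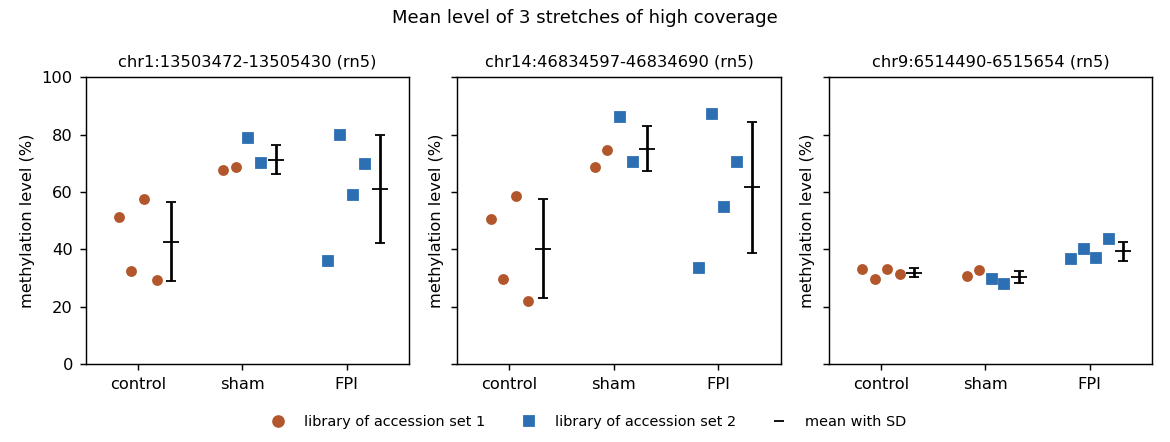
Mean methylation level in percent of 3 stretches of high coverage, with 1 point per library and the mean and SD beside each group, and coordinates on rn5. On chromosomes 1 and 14 sham averaged 71.2 and 74.96% and control 42.7 and 40.2%, and on chromosome 9 FPI averaged 39.4%, sham 30.2% and control 31.9%.

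No tile was called between sham and control among 8537 by the quasi-binomial model, limma or edgeR, with 499, 492 and 439 tiles at an unadjusted p under 0.05. The 6 tiles with the smallest p did not pass. They included 3 tiles of the chromosome 1 stretch, starting at 13503001, 13504001 and 13505001, with differences of 30.9, 31.6 and 32.5 points (adjusted p = 0.0768 each), and the tile of chromosome 14 starting at 46834001, with 34.8 points (adjusted p = 0.0857). The others were lower in sham. On chromosome 2, from 208429001 to 208430000, the level was 11.8% ± 2.84 in sham and 36.2% ± 5.71 in control, and on chromosome 15, from 3645001 to 3646000, it was 54.0% ± 10.8 and 85.5% ± 10.9 (SD, n = 4; adjusted p = 0.0768 in the model for both). On chromosome 2 all 3 dyads were lower in sham, with differences of -22.7, -29.3 and -21.7 points. On chromosome 15 a single dyad at 3645055 carried the difference, with 2.5% ± 5 in sham and 78.3% ± 20.1 in control (SD, n = 4), and was called by itself (adjusted p = 5.34e-10 in the quasi-binomial model). Leaving out sham 1 or control 3 gave 5 called tiles each. Without sham 1 the chromosome 15 tile had adjusted p = 0.0434 and that of chromosome 1 starting at 13505001 had 0.0386, and without control 3 the latter had 0.0122, its neighbours 0.000645 each and the chromosome 14 tile 0.00102.

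The comparison of FPI with control spans surgery and injury, and here all FPI libraries belonged to the second accession set and all control libraries to the first, so no value within a set can be given. The mean CpG level was 49.5% ± 0.259 in FPI and 49.9% ± 0.168 in control (SD, n = 4), a difference of -0.398 points (two-sided exact permutation p = 0.0286, adjusted p = 0.0857 over 3 comparisons). That p is the smallest possible, and alone at it this comparison could not pass after adjustment. Among classes of pooled level the difference was largest in dyads under 5%, where the means were 1.14% ± 0.464 and 2.45% ± 0.270 (SD, n = 4; exact permutation p = 0.0286, adjusted p = 0.214 over 30 tests). Too few of these 30 tests lay at the smallest possible p for any to pass. At 95% or more they were 97.3% ± 0.147 and 97.1% ± 0.0775 (exact permutation p = 0.0857). After correction for each library's non-CpG level the difference of the means was 0.311 points, in the other direction (exact permutation p = 0.0571). At a coverage minimum of 20 it was 0.101 points, and without FPI 3, control 1 or control 2 it was -0.274, -0.364 and -0.337 points (exact permutation p = 0.0857 each).

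Of 56954 dyads, 66 were called between FPI and control, 41 higher and 25 lower in FPI, on 18 chromosomes. Of these, 17 had high coverage, 14 of them on chromosome 1. The balance of directions varied. With the replicate block 11 were higher and 14 lower in FPI, without control 1 11 and 12, and without control 2 26 and 26. Without FPI 1 it was 177 and 70, and without FPI 3 189 and 61. No tile was called among 10548 by the quasi-binomial model, limma or edgeR, with 622, 680 and 599 at an unadjusted p under 0.05. The tile with the smallest p was the one on chromosome 15 starting at 3645001, with 58.3% ± 0.619 in FPI and 88.9% ± 8.53 in control (SD, n = 4; adjusted p = 0.108 in the model, and 0.0180 without control 4). The same dyad at 3645055 carried it, with 1.19% ± 2.38 against 78.3% ± 20.1 (SD, n = 4), and was called (adjusted p = 6.47e-09 in the quasi-binomial model). These comparisons share the control libraries. Among the other tiles, 2 of chromosome 2 were higher in FPI, starting at 216699001, with 44.0% ± 5.52 against 26.4% ± 3.96 over 9 dyads, and at 215787001, with 77.03% ± 3.74 against 60.04% ± 5.93 over 5 dyads (adjusted p = 0.266 and 0.278 in the model). The tile of chromosome 12 starting at 41189001 was also higher, 94.6% ± 2.46 against 75.5% ± 10.4 (adjusted p = 0.356 in the model). The tiles starting at 63024001 of chromosome 9 and at 107624001 of chromosome 6 were lower, with differences of -18.3 and -16.5 points (adjusted p = 0.278 and 0.320 in the model), and on chromosome 6 the dyad at 107624630 carried most of it (difference -61.5 points). Leaving out FPI 3 gave 3 called tiles and leaving out control 4 gave 1. Among the 45246 dyads covered in all 12 libraries that passed the filter on level, 12 were called without and 5 with a term for the accession sets, estimated through sham. Over all tested dyads the count was 6 by limma and 16 by edgeR, and leaving out FPI 1, FPI 2, FPI 3, control 1 or control 3 gave 247, 121, 250, 23 and 141.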

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

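The tests on non-CpG levels, on neighbouring CpGs and on sequence variants were chosen after the results were seen, while the counts over splits were set before. The correction of levels was added after the non-CpG levels were seen and before the corrected means were, and its reading by class of level came after. Of 60 groups of 4 libraries examined for a library far from the others, 6 held one, and chance gives about 1 in 20, or 3.00.

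Non-CpG levels were higher in the first accession set. Tables argue against non-CpG methylation of the cells, since CA, its main target, differed between the sets by less than CT (-0.482 points), and against the procedure, since sham 1 and sham 2 lay 1.92 points above sham 3 and sham 4. Incomplete bisulfite conversion stays open as a candidate explanation: mitochondrial cytosines differed between the sets by 1.53 points, about as much as autosomal ones. The same cause is consistent with the lower level of FPI than control at dyads under 5%, where the difference went from -1.31 to 0.0684 points with the correction. For the mean over all dyads it stays undecided. The difference went from -0.398 to 0.311 points, so it changed sign while its absolute size stayed over 50% of the first. The SD of the corrected means was 0.262 in FPI and 0.154 in control. Dyads of 20 to 80% went from 0.436 to 1.09 points and those of 80 to 95% from 0.271 to 0.414 points. A corrected difference between the sets remained (-0.315 points, exact permutation p = 0.00433, n = 6).

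The dyads called between FPI and sham stood mostly alone. A change shared by neighbouring CpGs is argued against by the median ratio of 0.00581, and incomplete conversion by the median absolute difference of 42.2 points, far above any non-CpG level. A sequence variant at the CpG in some rats, which are outbred, stays open and untested by genotype. Dyads at which every covered library lay within 15 points of 0, 50 or 100%, with at least 2 of these levels seen, were removed. This left 107371 of the 108066 dyads to test. Of these, 97 were called, 75 of them among the 94, so calls were lost in larger proportion than dyads. Also called were 2 tiles. The dyad at 86572055 was among those removed, so the chromosome 14 tile kept too few dyads to be tested. Library levels at called dyads lay within 15 points of 0, 50 or 100% in 86.2% of cases, against 51.5% for uncalled dyads of like pooled level. After this was seen, that comparison was repeated with uncalled dyads of like level and like spread, which gave 85.5%, and since wide uncalled dyads may be variants as well, neither comparison decides.

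Chance could not be excluded for the dyads of FPI against sham or FPI against control: 8 of the 35 splits of the 8 libraries gave at least the 94 dyads of FPI against sham, with 121 at most in another split, and 6 of 35 gave at least the 66 of FPI against control. The highest of the latter, 196 dyads, about 3 times the real count, joined FPI 1 with control 1, control 2 and control 4. In the stretch of chromosome 1 from 13503472 to 13505430 these lay at 35.9, 51.4, 32.5 and 29.4%. FPI 2, FPI 3, FPI 4 and control 3 lay higher there, at 79.7, 58.7, 69.8 and 57.4%. Which dyads made up the 196 was not examined. The 3 tiles of FPI against sham were reached by 1 of 35 splits, the real one, with 2 in the highest other. That is the smallest share that 35 splits can give. It rests on a margin of 1 tile, and the splits ignore the accession sets, so chance is not excluded for that count. Over the 8105 tiles covered in all 12 libraries that passed the filter on level, 2 were called without and 0 with a term for the sets. Without sham 1, sham 2 or sham 4 the full count was 1. For sham against control 1 of 35 splits gave 146 dyads, the real one, with 140 in the highest other. This too is the smallest possible share, by a margin of 6 dyads over splits that ignore the sets, and chance is not excluded. Over the 46379 dyads covered in all 12 libraries that passed the filter on level, 75 were called without and 5 with a term for the sets. With the term only sham 1 and sham 2 stand against control. Fitted without the other libraries, that contrast gave 151 calls over 47150 dyads. The fall to 5 therefore does not show a part of the sets in the count, which stays open. Of the 146 calls 92 lie in the stretch of chromosome 1 and the pair of stretches that varied with it, so the count rests largely on stretches that vary together. With 0 tiles called, all 35 splits gave as many in both other comparisons, with up to 2 between sham and control and up to 8 between FPI and control.

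FPI 1 stood apart from the other FPI libraries in non-CpG level, at 1.40%, and in mitochondrial non-CpG level, at 1.52%. Control 3 had a mitochondrial non-CpG level of 1.53%, below the other controls. In the corrected mean CpG level control 4 lay apart at 48.6%. In the tile of chromosome 14 starting at 86572001 FPI 1 lay apart at 64.8%. In the tile of chromosome 19 starting at 38560001 FPI 2 lay apart at 66.0%.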

How the results depend on the processing

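The correction for the non-CpG level, libraries of 1 set for mean levels, removal of high-coverage or genotype-like dyads and the single prior dispersion were chosen after the data were seen. A coverage minimum of 5 could not be run, since files list cytosines from 10 reads, and gene promoters and gene lists were not analysed. The cause of a change was not tested unless stated.

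Mean CpG level reversed at a coverage minimum of 20 (0.118 points for FPI against sham, 0.101 for FPI against control), after the correction (0.136, 0.176 and 0.311 for FPI against sham, sham against control and FPI against control) and within 1 accession set (0.117 for FPI against sham, 0.143 for sham against control). Within 1 set and corrected, these were -0.0259 and 0.0139 (exact permutation p = 0.933 and 1, smallest possible p 0.0667). With pooled reads FPI against control was -0.624 points, with exact permutation p = 0.429 against 0.0286 for the unweighted mean, whose adjusted p was 0.0857. Leaving out each library gave -0.342 to -0.0802 for FPI against sham, -0.318 to -0.056 for sham against control and -0.460 to -0.274 for FPI against control.

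Counts of dyads were, for FPI against sham, sham against control and FPI against control, 5, 60 and 3 at a coverage minimum of 20 (fewer dyads tested), 571, 231 and 347 with no filter on level (more dyads tested), 22, 75 and 12 in the fit to all 12 libraries (fewer dyads tested), 26, 5 and 5 in that fit with a term for the accession sets, 11, 3 and 6 by limma and 17, 90 and 16 by edgeR. With sham libraries of 1 set only, 126 dyads and 2 tiles were called for FPI against sham and 151 dyads and 0 tiles for sham against control. Thinning to 10 reads gave 22 and removal of high-coverage dyads 50 for sham against control. For FPI against control strands kept apart gave 115, removal of genotype-like dyads 108 and a single prior dispersion 28. Leaving out each library gave 99 to 158, 131 to 211 and 23 to 250.

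Counts of tiles for FPI against sham were 0 at a coverage minimum of 20 (1867 tiles tested, without the called tiles of chromosomes 14 and 6) and 0 thinned to 10 reads. They were 2 in the fit to all 12 libraries and 0 in that fit with a term for the accession sets (8105 tiles tested, also without those 2 tiles). A single prior dispersion gave 5, tiles of 500 and 2000 bp gave 2 and 3, and leaving out each library gave 1 to 7. For sham against control they were 5 with no filter, 3 thinned, 1 with a term for the sets and 0 to 5 leaving out each library. For FPI against control they were 1 with no filter, 1 in the fit to all 12 libraries and 0 to 3 leaving out each library. Of the called tiles, the one on chromosome 14 lost its call when thinned, out of 16 alternatives, the one on chromosome 6 under 11 of 17 and the one on chromosome 19 under 8 of 19, with no change of direction.

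The replicate numbers left no trace of pairing in the levels of tiles, which does not exclude a pairing by design. Deviations of same-numbered libraries correlated at -0.0171 to 0.0334 over 8207 tiles, and those of libraries with other numbers at -0.0345 to 0.0388. With the replicate block, 87, 92 and 25 dyads and 4, 8 and 0 tiles were called in the 3 comparisons. At the deposited depth, on simulated counts for FPI against sham, 22% of dyads and 80% of tiles changed by 20 points were called. Thinning the real counts to 10 reads gave 106 dyads, against 94, and 0 tiles, against 3.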

Other observations

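The stretches of high coverage and every test on them were chosen after the data were seen. There were 32 such stretches of at least 10 dyads, 728 dyads in all, with a median range of 10.6 points over the 12 libraries, and 4 of them had a range of at least 20 points. On chromosome 9, from 6514490 to 6515654, 41 dyads averaged 39.4% ± 3.31 in FPI, 30.2% ± 2.09 in sham and 31.9% ± 1.69 in control (SD, n = 4), and every FPI library lay above every other library (exact permutation p = 0.0286 against either group, adjusted p = 0.549 over 96 tests, of which too few lay at the smallest possible p for any to pass). On chromosome 13, from 95677901 to 95678490, 20 dyads averaged 30.3% ± 5.14 in FPI, 23.3% ± 4.72 in sham and 23.0% ± 1.36 in control (SD, n = 4; exact permutation p = 0.0571 and 0.0857, adjusted p = 0.645 for both). The dyad of chromosome 15 at 3645055 had 2.5% ± 5 in sham and 1.19% ± 2.38 in FPI, against 78.3% ± 20.1 in control (SD, n = 4), and was called against control in both comparisons (adjusted p = 5.34e-10 for sham and 6.47e-09 for FPI in the quasi-binomial model), which share the control libraries, while its tile passed in neither.

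The stretch of chromosome 1 from 13503472 to 13505430, higher in sham than in control, was compared with the other 31 stretches over the 12 libraries. The one on chromosome 14 from 46834597 to 46834690 varied alike (Pearson r = 0.993, permutation p = 1e-05, the smallest possible, adjusted p = 0.00031, Spearman rho = 0.965, permutation p = 1e-05). Without control 2 and control 4, the libraries farthest from the median, r was 0.987, and within the accession sets r was 0.996 and 0.988 (n = 6 each, exact permutation p = 0.00139 and 0.00278). A neighbour on chromosome 1 from 13500338 to 13500441 followed too (r = 0.905, permutation p = 2e-05, adjusted p = 0.00031), and none of the remaining stretches passed. A sequence present in many copies is possible, with coverage at least 5.24 times the median in each library, but the stretch was chosen for high coverage. The same sequence mapped on both chromosomes was searched for in the pattern of cytosines, where the best place shared 64.4% of the bases compared, but only 62.5% of the known bases could be compared. The accession sets are argued against as the whole cause: they would need sham 3 and sham 4 to exceed sham 1 and sham 2 by 57.1 points, and these differed by 6.30, while sham 1 and sham 2 averaged 25.4 points above the controls of their own set. The surgery itself stays open as untested, as does variation between rats.

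Over the 12 libraries 2333 dyads, 1.95% of those covered in all, had a range of at least 50 points, against 902 expected from sampling around the pooled level alone.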
